A study of Arabidopsis thaliana with 18 samples.

How the data were processed

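The series holds mRNA sequencing of whole Arabidopsis thaliana plants in the Col-0 accession. Per the labels, plants were grown in vitro for 11 days after germination with 18 h of light and 6 h of dark at 22 °C, and a company built the libraries and sequenced them on a HiSeq2000. The 18 libraries fall into 7 groups by their titles. With wild-type DCL genes, 35S-RTL2 (n = 3) and 35S-RTL1-Myc (n = 2) carry an RNase III-like gene under the viral 35S promoter, and rtl2-1 (n = 3) is a mutant of RTL2. The dcl234 mutant (n = 3) is mutated in the Dicer-like genes DCL2, DCL3 and DCL4, and it was also sequenced with 35S-RTL2 (n = 3) and with a truncated DCL1 driven by 35S (n = 1). Col-0 (n = 3) is the wild type. Nothing in the labels says whether replicates came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

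The deposited values are raw read counts, 1 whole number per row and library, made by the authors on the TAIR9 build per the submitters' processing notes. The aligner, the counter, its filters and its use of strand are not given in the sources used here. Each library has 31362 rows, and 1897 of these join 2 or more overlapping genes, which together took a median of 13.6% of a library's counts. Such rows are named by all their genes, and a change in one cannot be given to a single member. Reads of antisense partners cannot be told apart either. Across rows the libraries hold 33378 genes, and 32701 of them have an entry in the RefSeq table of assembly TAIR10.1, which gave the symbols. No coordinates are printed, since the builds differ. Total counts per library ran from 20775728 to 34874423. Of the mitochondrial rows, 29 passed the filter, and 0 chloroplast rows were present. Replicates correlated at r = 0.964 to 0.993 on log2 CPM across genes within a group, and every pair differed by more than sampling noise, with a chi-square per degree of freedom of at least 4.91, so no pair looked like 1 library deposited in duplicate, which does not tell whether the replicates are biological.

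Rows with few counts were removed with edgeR's filterByExpr, which left 21343. Libraries were scaled by the TMM method and fitted with edgeR 4.0.16 (glmQLFit and glmQLFTest) in R 4.3.3, in 1 model with a mean per group over all 18 libraries, so that all groups share the estimate of spread. This sharing gives the single truncated DCL1 library a test: the lone library is assumed to vary like the other groups, and the comparison has no replicate check. The contrasts tested were 35S-RTL2, rtl2-1, 35S-RTL1-Myc and dcl234 against Col-0, 35S-RTL2 and truncated DCL1 within dcl234 against dcl234, and the difference of the RTL2 effect between dcl234 and Col-0. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 over all rows tested. Fold changes are log2 with standard errors (SE) from the quasi-likelihood F statistic, and levels are TMM-scaled CPM, the usual unit of counts relative to library size, with the SD over replicates. A fold against a group with 0 counts is a lower bound against 3 counts over the group. The biological coefficient of variation from the common dispersion was 15.1%.

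The groups, tests, gene lists, named-gene rule and most alternatives were fixed before the data were examined. Named genes are RTL1, RTL2 and the 4 DCL genes. To these come up to 8 higher and 8 lower calls with the largest fold, a mean of at least 1 CPM and no overlap between groups, and up to 4 members with the smallest adjusted p from each list with a call. With fewer than 5 calls, all calls and the 5 smallest unadjusted p are named. The 21 fixed lists hold 330 entries for 328 genes, of which 1 was absent and 31 were removed by the filter. They cover the construct and mutated genes, RNA silencing factors, loci repressed by DNA methylation, trans-acting siRNA precursors and their targets, microRNA targets, salicylic acid defence, jasmonate and wound response, and anthocyanin and flavonoid synthesis. Further lists are photosynthesis, cold, drought and abscisic acid, heat shock, iron deficiency, phosphate starvation, sulfur starvation, the circadian clock, root markers, floral organ markers, flowering time, seed storage and the nucleolus. Of the listed genes measured, 36 lie in rows with another gene. Lists of at least 5 measured genes were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over lists within a comparison, and again with an estimated correlation. Gene classes by RefSeq type or genome (mitochondrial genes, pseudogenes, transcribed pseudogenes, long non-coding RNAs, other non-coding RNAs, microRNA precursors and small nucleolar RNAs) were tested in the same way.

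The main edgeR fit and camera with its preset correlation were tested on simulated counts drawn from the real means and library sizes. DESeq2 was tested so for RTL2 overexpression alone. In each simulated comparison 200 genes were changed. The other alternative fits, the splits and camera with an estimated correlation were not tested in this way. In the simulated RTL2 overexpression comparison over 21177 genes, 92.4% of 4-fold, 64.2% of 2-fold and 46.3% of 1.5-fold changes were called. For the simulated truncated DCL1 comparison over 21113 genes the shares were 77.3%, 49.3% and 16.4%. Alternatives were DESeq2's size factors (RLE scaling), no filter, DESeq2 1.42.0 as the test, a fit with the compared groups only, the replicate number as a block, the number 1, 2 or 3 that the deposited tables carry as a possible batch, organelle genes left out, a minimum log2 fold of 1, and each replicate left out in turn. Overlaps of comparisons that share Col-0 were set beside 20 simulations of unchanged groups. Small RNA data were not analysed here.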

Results

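Messenger RNA was sequenced from whole plants of wild-type Arabidopsis (Col-0), an RTL2 mutant, 35S overexpressors of RTL1 and RTL2, and the dcl234 triple mutant with and without RTL2 or truncated DCL1. RTL1 and RTL2 are RNase III-like proteins, and the DCL proteins cut double-stranded RNA into small RNAs. The 18 libraries held 20775728 to 34874423 counts each. Replicates were 3 per group except for 35S-RTL1-Myc with 2 and truncated DCL1 with 1. On log2 CPM, the first principal component held 37.1% of the variance and the second 19.1%. The library of rtl2-1 replicate 2 had the lowest mean correlation with its own group, r = 0.966 across genes.

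The altered genes were measured first. RTL1 stood at 1555 ± 42.4 CPM (SD, n = 2) in 35S-RTL1-Myc plants and at 0.388 ± 0.202 CPM (n = 3) in Col-0. RTL2 reached 557 ± 53.4 CPM (n = 3) in 35S-RTL2 plants and 1829 ± 199 CPM (n = 3) in dcl234 35S-RTL2 plants, against 2.93 ± 0.0432 CPM in Col-0 and 0.409 ± 0.159 CPM in rtl2-1 (n = 3 each). DCL1 is counted in 1 row with PPa1 and MIR838. That row stood at 1417 CPM in the truncated DCL1 library and at 149 ± 4.79 CPM in dcl234 (n = 3). In dcl234 the row of DCL2 with AT3G03305 held 41.6 ± 1.04 CPM, and the row of DCL3 with AT3G43930 held 3.24 ± 0.597 CPM. The Col-0 values were 69.9 ± 6.27 and 20.3 ± 1.31 CPM. DCL4 did not differ detectably between dcl234 (28.1 ± 3.26 CPM) and Col-0 (31.8 ± 4.29 CPM), and a mutation need not change the transcript level of its gene.

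**Figure D1:**
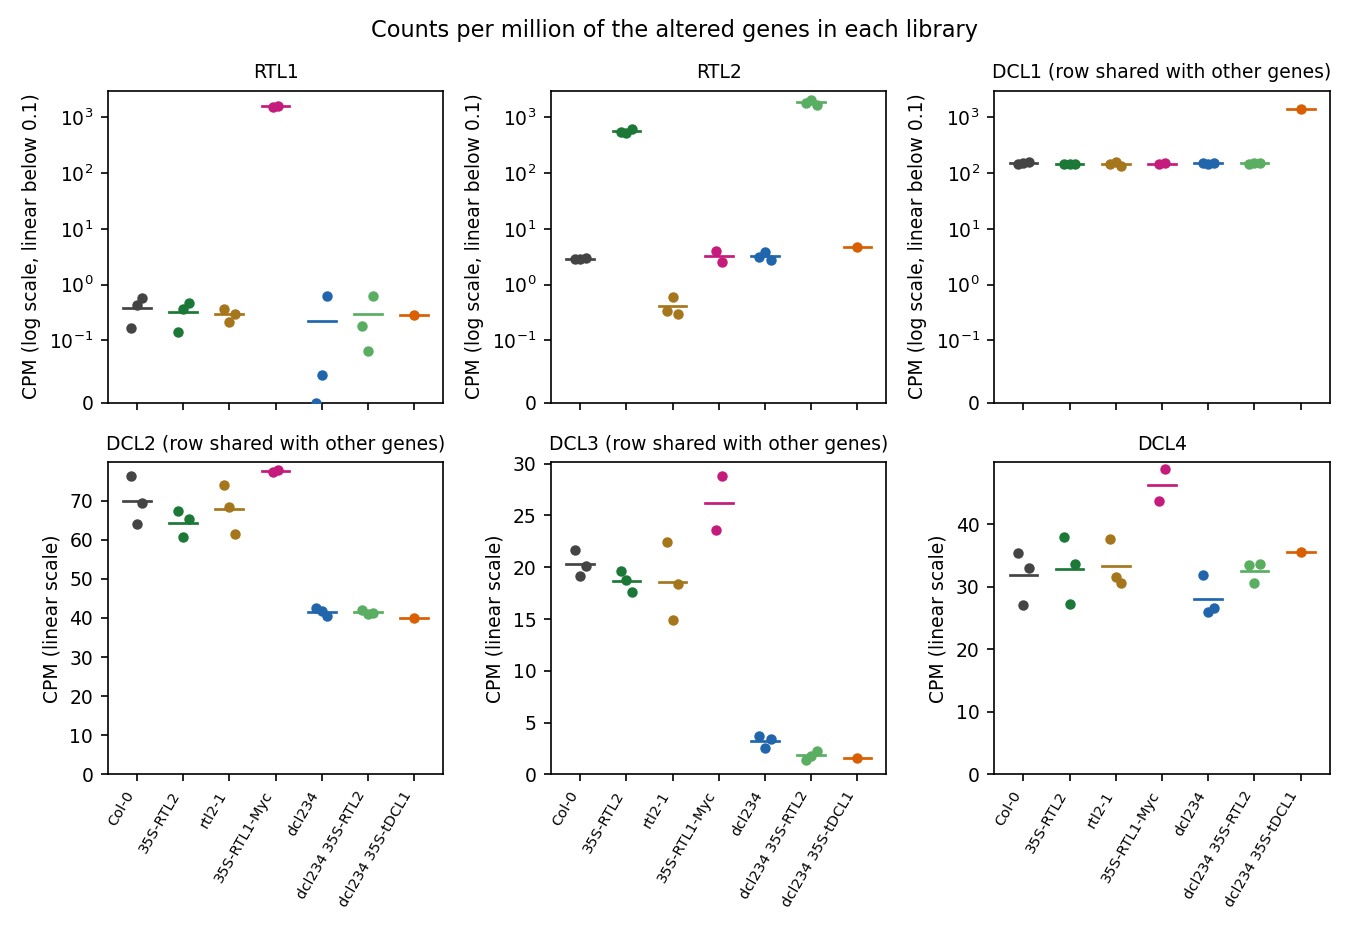
CPM of the altered genes in each library, by group, where points are libraries and short lines are group means. The axis is logarithmic above 0.1 CPM for RTL1, RTL2 and DCL1 and linear for DCL2, DCL3 and DCL4. RTL1 reaches a mean of 1555 CPM in 35S-RTL1-Myc plants, and the DCL1 row reaches 1417 CPM in the truncated DCL1 library.

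The comparison of 35S-RTL2 with Col-0 asked which transcripts differ when RTL2 is overexpressed. Apart from RTL2 itself, QQS was lower. QQS is a gene found in Arabidopsis alone that affects starch content and whose expression varies with DNA methylation. It stood at 1.54 ± 0.251 CPM in 35S-RTL2 plants and 10.7 ± 1.35 CPM in Col-0 (n = 3 each), a log2 change of −2.79 (SE 0.29), with all 35S-RTL2 libraries below all Col-0 libraries. RTL2 rose by 7.57 (SE 0.20). Adjusted p from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was 8.93e-12 for RTL2 and 0.00101 for QQS.

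No other gene passed among 21343 tested, so 2 were called, 1 higher and 1 lower. An unadjusted p below 0.05 was found for 956, a share below the 0.05 that unchanged genes alone would give. The 5 genes with the next smallest p did not pass. Their log2 changes were 1.02 (SE 0.15) for AT5G35935, 0.72 (SE 0.14) for OFP12, −1.35 (SE 0.27) for AT4G04223, −2.04 (SE 0.42) for AIG1 and −2.26 (SE 0.47) for AT3G33528. Their adjusted p from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was 0.0619 for the first and 0.71 for each of the others. Outside the construct genes and the methylation-repressed loci, which hold RTL2 and QQS, 0 members of the 19 other fixed lists were called by edgeR's test. Adjusted over the list alone, 1 salicylic acid defence gene of 19 was lower. DESeq2 called 6 genes.

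As sets, 4 lists passed camera with its preset correlation in this comparison and none passed with an estimated correlation. The 19 salicylic acid defence genes, which include pathogenesis-related proteins, had a median log2 of −0.39 (camera adjusted p = 5.85e-05, and adjusted p = 0.296 with an estimated correlation). Libraries of both groups differed in this list: its median log2 CPM was 1.13 in Col-0 replicate 2, which lay 1.89 from the rest of its group, and 1.16, 0.92 and 2.11 in 35S-RTL2 replicates 1, 2 and 3. The 17 photosynthesis genes had a median of −0.24 (camera adjusted p = 0.000144, and adjusted p = 0.556 with an estimated correlation). Medians were 0.87 for the 9 sulfur starvation genes (camera adjusted p = 2.48e-05, and adjusted p = 0.296 with an estimated correlation) and 0.08 for the 57 microRNA targets (camera adjusted p = 0.00544, and adjusted p = 0.0581 with an estimated correlation). The 29 mitochondrial genes had a median of 0.94 (camera adjusted p = 4.17e-07, and adjusted p = 0.638 with an estimated correlation). Their share of counts was 0.00743% and 0.00518% in 35S-RTL2 replicates 1 and 3, but 0.00322% in replicate 2, against 0.00292% to 0.00312% in Col-0.

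In rtl2-1 plants AT3G01345 was the gene with the largest change. It stood at 284 ± 39.4 CPM, against 0.124 ± 0.0486 CPM in Col-0 (n = 3 each), a log2 change of 11.13 (SE 0.94). CYP97B3, a cytochrome P450 of the carotenoid hydroxylase family, fell from 67.2 ± 4.19 to 15.8 ± 3.88 CPM (log2 −2.08, SE 0.14). RTL2 fell by 2.85 on the log2 scale (SE 0.26), AT5G35935 by 2.70 (SE 0.21) and QQS by 2.05 (SE 0.27). Higher calls included NAC044, a NAC transcription factor, at 3.17 (SE 0.29), and AT2G35570 at 3.77 (SE 0.38). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the adjusted p was 4.77e-05 for AT3G01345, 5e-06 for CYP97B3, 8.93e-05 for RTL2 and for NAC044, and 0.00471 for QQS.

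In all, 26 genes were called, 16 higher and 10 lower. Among the named higher calls, AT4G05380 rose by 1.68 (SE 0.25), AT1G17960 by 1.64 (SE 0.29), AT2G13550 by 1.27 (SE 0.17) and AT1G23410 by 1.14 (SE 0.12). AT2G03970 was near 0 in Col-0, at 0.0139 ± 0.0241 CPM, and stood at 3.8 ± 1.14 CPM in rtl2-1. Among the lower calls were AT1G28305 (log2 −1.45, SE 0.25), AT3G15640 (log2 −0.94, SE 0.15), AT1G22550 (log2 −0.87, SE 0.15) and AT3G09720 (log2 −0.51, SE 0.08). The count differed between settings: only AT3G01345 passed when the compared groups were filtered, scaled and fitted alone, 15 genes passed with the table number as a batch term, and DESeq2 called 137. Leaving out single libraries gave 12 calls without Col-0 replicate 3, 14 without Col-0 replicate 2, 15 without Col-0 replicate 1 or rtl2-1 replicate 2, 44 without rtl2-1 replicate 3 and 54 without rtl2-1 replicate 1.

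Of the 19 salicylic acid defence genes, 1 was lower in rtl2-1: AIG1 (log2 −2.52, SE 0.44; adjusted p = 0.0374 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), at 0.0759 ± 0.031 against 0.468 ± 0.148 CPM. AIG1 passed in 4 of 13 alternatives, and of the 17 calls named for rtl2-1, 1 passed under every setting run on single genes, to which the minimum fold was not applied. Adjusted over the list alone, 5 were lower, and the list's median was −0.79 (camera adjusted p = 6.06e-07, and adjusted p = 0.141 with an estimated correlation). The list's median log2 CPM was 0.76 to 1.34 in the rtl2-1 libraries, and Col-0 replicate 2, at 1.13, lay within that range and 1.89 from the rest of its group. Of the 6 nucleolus and ribosome biogenesis genes, 0 passed over all genes and 5 were higher when adjusted over the list alone (median 0.35, camera adjusted p = 2.33e-05, and adjusted p = 0.141 with an estimated correlation). Medians were −0.20 for jasmonate genes (camera adjusted p = 0.00492, and adjusted p = 0.436 with an estimated correlation) and −0.33 for anthocyanin genes (camera adjusted p = 0.00675, and adjusted p = 0.601 with an estimated correlation). For microRNA targets the median was 0.10 (camera adjusted p = 0.0308, and adjusted p = 0.141 with an estimated correlation), and for the construct genes −0.10 (camera adjusted p = 0.0418, and adjusted p = 0.249 with an estimated correlation). The 34 small nucleolar RNAs had a median of 0.43 (camera adjusted p = 3.29e-05, and adjusted p = 0.845 with an estimated correlation). The rtl2-1 replicate that stood farthest from its group enters all of these values.

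With RTL1-Myc overexpressed, more genes were called than in any other comparison, 6289 in all, with 3155 higher and 3134 lower. Clock genes shifted in these libraries, and the hour of harvest is not in the labels. For genes other than RTL1, an effect of the construct therefore cannot be told apart from a shift of that hour by group. The same limit holds for the lists of this comparison that follow. GSTF11, a glutathione transferase, rose by 5.64 (SE 0.57), from 0.261 ± 0.0789 CPM (n = 3) to 13.1 ± 2.93 CPM (n = 2). PORA, a protochlorophyllide oxidoreductase of chlorophyll synthesis, fell by 5.89 (SE 0.64), from 26.2 ± 5.14 to 0.434 ± 0.204 CPM. Among trans-acting siRNA targets 11 were higher and 1 lower, and among microRNA targets 20 were higher and 8 lower. Of the clock genes 7 were higher and 9 lower, and of the photosynthesis genes 0 were higher and 5 lower, by edgeR's test. Since 29.5% of all genes tested were called in this comparison, a list with a similar share does not stand out by its count. Among the clock genes, LHY, a morning-phased transcription factor, rose from 3.82 ± 0.605 to 127 ± 31.7 CPM.

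Among the largest calls, RTL1 rose by 11.93 (SE 0.51), AT2G46940 by 5.98 (SE 0.70), AT2G35570 by 5.60 (SE 0.39) and AT5G37970 by 5.47 (SE 0.61). PDF1.3, a plant defensin, had 0 counts in Col-0 and was at least 66.9-fold higher in 35S-RTL1-Myc plants, where its 2 libraries differed widely (2.57 ± 3.44 CPM). PDF1.3 was not called without 35S-RTL1-Myc replicate 2. AT2G04135 and AT2G03130 stood at 2.89 ± 0.473 and 2.48 ± 0.43 CPM, and were near 0 in Col-0. On the lower side were AT1G62760 (log2 −7.06, SE 0.67), RR22 (log2 −4.82, SE 0.77), a response regulator of cytokinin signalling, and the row of AT1G63057 and AT1G63055 (log2 −4.75, SE 1.14). AT5G63170, AT3G19940, AT2G31540 and AT1G61688 lay between 1.7 and 2.41 CPM in Col-0 and at no more than 0.0362 CPM in 35S-RTL1-Myc plants. The adjusted p of edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was 9.13e-09 for RTL1, 7.91e-06 for GSTF11, 1.27e-05 for PORA and 0.00364 for PDF1.3.

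Of the 34 RNA silencing factors, 8 were higher and 3 lower, and adjusted over the list alone 9 were higher and 3 lower. AGO2, an Argonaute of antiviral defence, rose by 1.37 (SE 0.14), NRPD1, the largest subunit of RNA polymerase IV, by 1.25 (SE 0.24), and SGS3, a cofactor of double-stranded RNA synthesis, by 0.55 (SE 0.09). ROS1, a DNA demethylase, fell by 1.46 (SE 0.13), from 120 ± 13.7 to 43.6 ± 6.09 CPM. DCL4 rose by 0.54 (SE 0.14). As a set the silencing factors did not pass (camera adjusted p = 0.0728). Of 7 trans-acting siRNA precursors, 3 were higher and 0 lower, both over all genes and adjusted over the list alone: TAS3 by 1.46 (SE 0.20), TAS2 by 1.04 (SE 0.18) and the row of TAS1C with AT2G39670 by 0.59 (SE 0.16). The camera adjusted p of that list was 0.117.

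Targets of trans-acting siRNAs and microRNAs followed. Of 23 trans-acting siRNA targets, 11 were higher and 1 lower (12 and 1 adjusted over the list alone), with a median log2 of 0.52. ARF4, an auxin response factor, rose by 1.63 (SE 0.09), from 45.6 ± 2.53 to 141 ± 5.03 CPM, HTT2 by 1.18 (SE 0.11) and AT1G63130 by 0.67 (SE 0.09). The row of UGE1 and AT1G12775 fell by 0.80 (SE 0.13), and its reads may come from either gene. The list's camera adjusted p was 0.000249, and its adjusted p = 0.224 with an estimated correlation. Of 57 microRNA targets, 20 were higher and 8 lower (21 and 9 adjusted over the list alone). TOE2, a repressor of flowering targeted by miR172, rose by 2.15 (SE 0.11), AGL16 by 1.85 (SE 0.19), GRF1, a growth-regulating factor, by 1.35 (SE 0.13) and ARF10 by 0.62 (SE 0.07). This list's camera adjusted p was 0.00727, and it held with an estimated correlation at 0.048, the only list call of this comparison that did. Adjusted p from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was 3.11e-08 for ARF4 and 2.99e-08 for TOE2.

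Of 17 clock genes, 7 were higher and 9 lower, the same numbers as adjusted over the list alone. LHY rose by 5.05 (SE 0.27), RVE8 by 4.17 (SE 0.28), PRR9 by 2.93 (SE 0.25) and LNK1 by 1.64 (SE 0.13). The list's median was −1.03 and its mean 0.37, so they differ in sign. FLC, a repressor of flowering, rose by 2.66 (SE 0.20), from 1.09 ± 0.107 to 6.98 ± 0.0937 CPM. FT, the mobile flowering signal, fell by 2.75 (SE 0.45), from 39.8 ± 5.27 to 5.91 ± 0.604 CPM. With FUL (0.34, SE 0.12), 2 of 6 flowering genes were higher and 1 lower, also adjusted over the list alone. Without 35S-RTL1-Myc replicate 1, FUL stood at 0.15 and was not called. The 0 calls for the 8 floral organ markers were made by edgeR's test. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the adjusted p was 3.11e-08 for LHY, 6.96e-07 for FLC and 0.000357 for FT.

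Of 17 photosynthesis genes, 5 were lower and 0 higher, also adjusted over the list alone. RBCS2B and RBCS1B, small subunits of Rubisco, fell by 1.17 (SE 0.16) and 0.97 (SE 0.19), and the antenna genes LHCB1.3 and LHCA2 by 1.02 (SE 0.20) and 0.65 (SE 0.15). The list's camera adjusted p was 0.00727, and its adjusted p = 0.628 with an estimated correlation. Of 16 anthocyanin and flavonoid genes, 6 were higher (8 adjusted over the list alone). Among them were CHI (1.22, SE 0.29), 5MAT (1.47, SE 0.39), the row of F3H with AT3G51238 (1.32, SE 0.17) and the row of CHS, chalcone synthase, with AT5G13940 (1.21, SE 0.23). The camera adjusted p was 0.0369, and the adjusted p = 0.628 with an estimated correlation. Of 6 nucleolar genes, 4 were lower and 1 higher, also adjusted over the list alone, with NUC1, the nucleolin, at −0.75 (SE 0.15), the row of FIB2, a fibrillarin, at −0.93 (SE 0.19), CBF5 at −0.50 (SE 0.11) and NOP56 at −0.45 (SE 0.12).

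Of 15 jasmonate genes, 5 were higher and 0 lower, also adjusted over the list alone, among them PDF1.2, a defensin (4.94, SE 0.76), AOC1 (2.04, SE 0.28) and AOS (0.92, SE 0.13), which make jasmonate, and the regulator MYC2 (0.86, SE 0.13). Of 15 cold, drought and abscisic acid genes, 5 were higher, also adjusted over the list alone, with RD20 at 1.74 (SE 0.19), RD29B at 4.06 (SE 1.14), RD22 at 0.69 (SE 0.11) and ERD10 at 0.46 (SE 0.13). Of 9 heat shock genes, 3 were higher, also adjusted over the list alone: HSP18.2 (1.32, SE 0.15), HSP17.6II (2.11, SE 0.69) and the row of HSP101 (0.96, SE 0.09). The heat list's camera adjusted p was 0.0436, and its adjusted p = 0.628 with an estimated correlation. The jasmonate list and the cold, drought and abscisic acid list did not pass camera, nor did the salicylic acid list. The counts in these lists stand beside 29.5% called over all genes. Of 19 salicylic acid defence genes, 4 were higher and 3 lower, also adjusted over the list alone. PAD4 was at 0.90 (SE 0.24), SARD1 at 1.31 (SE 0.42), PR5 at 0.93 (SE 0.31) and EDS1 at −0.64 (SE 0.15). The 35S-RTL1-Myc libraries differed here: without replicate 2, PR5 stood at a log2 of 0.02 and was not called, and PDF1.2 at 3.10.

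Of 9 sulfur starvation genes, 3 were higher and 0 lower (4 and 0 adjusted over the list alone), with LSU1 at 3.07 (SE 0.62), APR1, the reductase of sulfate assimilation, 2.63-fold higher (SE 0.38 on the log2 scale) and LSU2 at 1.36 (SE 0.47). Of 9 iron deficiency genes, 3 were higher and 1 lower (4 and 1 adjusted over the list alone), with the iron transporter IRT1 at 1.33 (SE 0.16), NAS4 at 2.04 (SE 0.53), PYE at 0.49 (SE 0.14) and ORG1 at −0.42 (SE 0.12). Of 9 phosphate starvation genes, 3 were higher and 3 lower, also adjusted over the list alone: MGD3 (−1.32, SE 0.31) and SQD2 (−0.28, SE 0.08) were lower, and PHT1;4 (0.96, SE 0.26) and SQD1 (0.49, SE 0.13) higher. Of 7 root markers, 1 was higher and 1 lower (2 and 1 adjusted over the list alone). These were PRP3 at 1.53 (SE 0.53) and COBL9 at −1.81 (SE 0.56). None of the sulfur, iron, phosphate and root lists passed camera, and 29.5% of all genes were called in this comparison. Of 6 methylation-repressed loci measured, 3 were higher and 1 lower, also adjusted over the list alone, with the F-box gene SDC at 1.93 (SE 0.40), IG/LINE at 0.562 ± 0.0244 CPM against 0.0279 ± 0.0483, the row of AT1G11270 and AT1G11265 at 0.42 (SE 0.12) and QQS at −3.45 (SE 0.35).

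With 2 libraries in this group, leaving out 1 moved the count to 3939 (without 35S-RTL1-Myc replicate 1) or 4151 (without replicate 2), where the lone library is assumed to vary like the other groups. A minimum log2 fold of 1 left 2518 calls. Of the 83 calls named here, 55 passed under every setting run on single genes, which leave out the minimum fold, and the other 28, which include DCL4, PR5, SARD1, PAD4, EDS1, FUL, PRP3 and the TAS1C row, did not pass in at least 1.

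**Figure D2:**
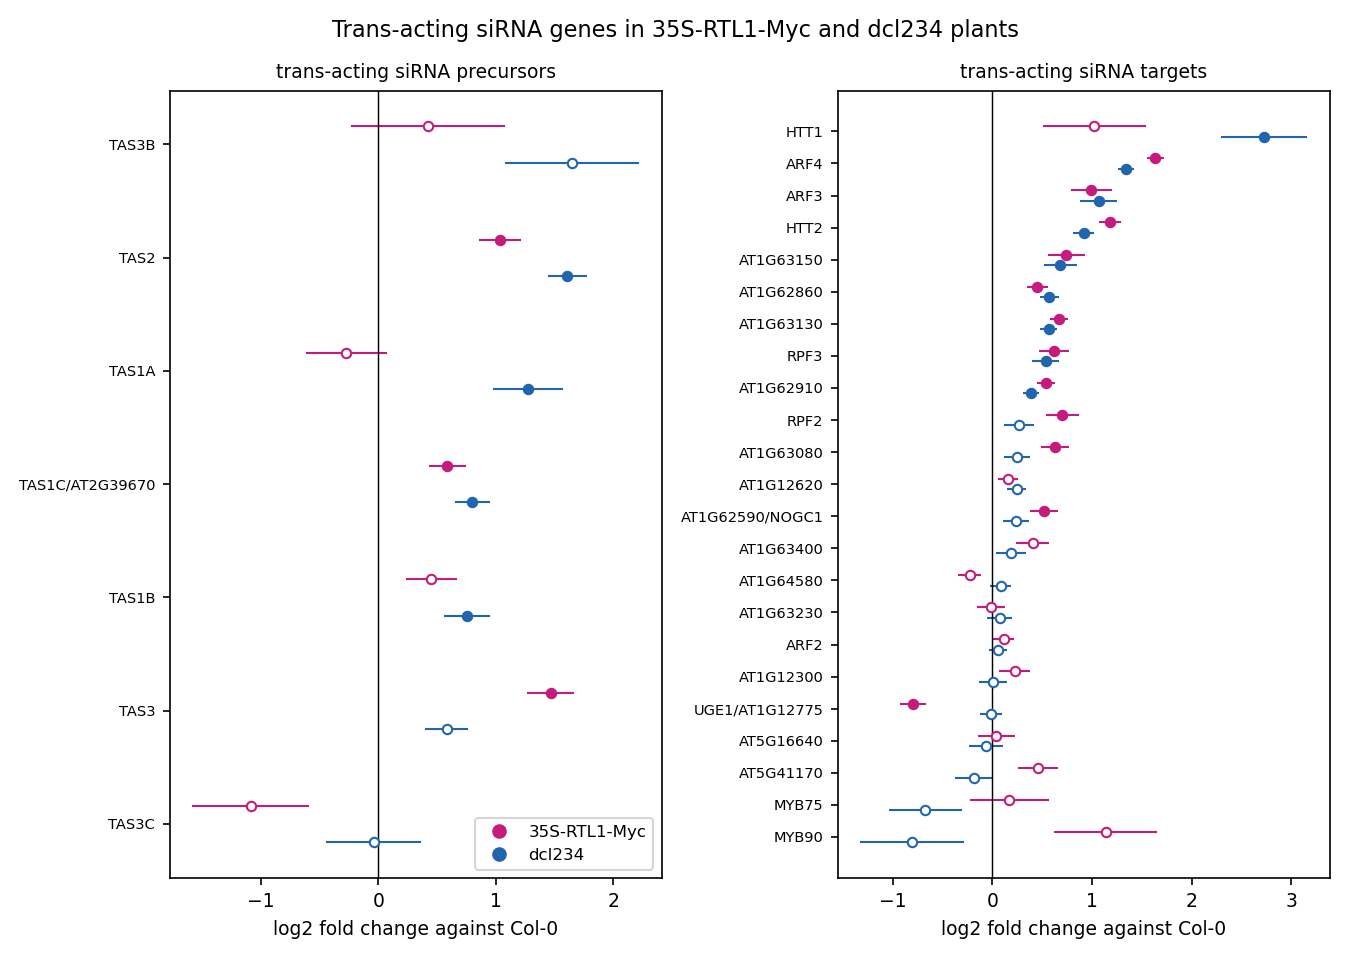
Log2 fold change against Col-0 of the trans-acting siRNA precursors and targets in 35S-RTL1-Myc and dcl234 plants. Bars are standard errors, filled points passed an adjusted p of 0.05 and open points did not. ARF4 lies at 1.63 in 35S-RTL1-Myc and 1.34 in dcl234.

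In dcl234 plants most called genes were lower than in Col-0. ROS1 fell from 120 ± 13.7 to 27.3 ± 1.26 CPM (n = 3 each; log2 −2.14, SE 0.11). FLC rose by 1.47 (SE 0.20), from 1.09 ± 0.107 to 3.04 ± 0.575 CPM, and FT fell by 1.49 (SE 0.36), from 39.8 ± 5.27 to 14.2 ± 1.89 CPM. Higher calls included 4 of 7 trans-acting siRNA precursors and 9 of 23 of their targets, and lower calls 3 of 16 anthocyanin genes. The call total was 973, with 161 higher and 812 lower. The adjusted p of edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was 1.04e-07 for ROS1, 0.00133 for FLC and 0.028 for FT.

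Of 7 trans-acting siRNA precursors, 4 were higher in dcl234 (6 adjusted over the list alone): TAS2 (1.61, SE 0.17), TAS1A (1.27, SE 0.30), the row of TAS1C (0.80, SE 0.15) and TAS1B (0.75, SE 0.20). The list's median was 0.80, its camera adjusted p was 3.6e-06, and its adjusted p = 0.132 with an estimated correlation. Of 23 targets, 9 were higher and 0 lower (10 and 0 adjusted over the list alone). HTT1 rose by 2.73 (SE 0.43), ARF4 by 1.34 (SE 0.08), HTT2 by 0.92 (SE 0.10) and AT1G63130 by 0.56 (SE 0.08). The camera adjusted p was 8.46e-08, and the adjusted p = 0.0878 with an estimated correlation. GRF9 was the only microRNA target of 57 to pass over all genes (0.84, SE 0.22), and adjusted over the list alone 0 did by edgeR's test. Adjusted p from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was 3.63e-07 for ARF4, 0.00292 for HTT1 and 0.000166 for TAS2.

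Of 16 anthocyanin genes, 3 were lower and 0 higher (4 and 0 adjusted over the list alone): DFR (−3.49, SE 0.80), LDOX (−3.08, SE 0.63) and UGT79B1 (−2.06, SE 0.41), all enzymes of the late steps. The list's camera adjusted p was 0.00119, and its adjusted p = 0.49 with an estimated correlation. Of 34 silencing factors, 2 were lower, also adjusted over the list alone, ROS1 and NRPD1 (−0.86, SE 0.23). Of 6 construct genes, 2 were lower, also adjusted over the list alone, the DCL3 row (−2.64, SE 0.18) and the DCL2 row (−0.75, SE 0.08), and that list's camera adjusted p was 0.00237, and its adjusted p = 0.0984 with an estimated correlation. Of 6 methylation-repressed loci, SDC rose by 1.48 (SE 0.38), while QQS fell by 1.23 (SE 0.26) and FWA, an imprinted homeobox gene, by 3.05 (SE 0.79), 1 higher and 2 lower also when adjusted over the list alone. JAZ1, a repressor of jasmonate signalling, was the 1 lower jasmonate gene of 15 (−0.54, SE 0.14), also adjusted over the list alone. With SOC1 (0.31, SE 0.08), 2 of 6 flowering genes were higher and 1 lower, also adjusted over the list alone.

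The largest higher calls in dcl234 were AT3G01345 (6.51, SE 1.02), AT3G28899 (2.04 ± 0.782 CPM, near 0 in Col-0), CSLB06, a cellulose synthase-like gene (4.15, SE 0.61), AT5G35935 (3.21, SE 0.15), AT5G19880 (2.55, SE 0.48), AT4G04223 (2.51, SE 0.23), AT4G11290 (2.28, SE 0.47) and AT1G53010 (2.11, SE 0.42). AT3G01345 varied widely between the dcl234 libraries, at 11.8 ± 13.2 CPM. The largest lower calls were the row of AT1G63057 and AT1G63055 (−6.31, SE 1.17), SCRL10 (−5.53, SE 1.05), EXPA25, an expansin (−5.30, SE 0.93), AT4G15750 (−5.27, SE 0.98), AT4G35725 (−5.24, SE 0.89), scpl21 (−5.24, SE 1.06), AT2G30810 (−5.18, SE 1.09) and AT1G13605 (−5.15, SE 1.09). In dcl234 these lower genes held 0.0462 to 0.762 CPM. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the adjusted p was 4.52e-08 for AT5G35935 and 0.0057 for EXPA25. The 102 other non-coding RNAs had a median of 0.09 (camera adjusted p = 0.0428, and adjusted p = 0.692 with an estimated correlation).

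The number of calls in dcl234 depended on the settings more than their direction did. The count was 149 with the table number as a batch term, 3336 with the compared groups alone (34.3% higher, against 16.5%) and 518 with a minimum log2 fold of 1. With 1 library left out it ran from 282 to 562. It was 282, 428 and 562 without dcl234 replicates 1, 2 and 3, and 427, 510 and 561 without Col-0 replicates 1, 2 and 3. The table number was 1, 1 and 3 in dcl234 replicates 1, 2 and 3, and 2, 3 and 2 in those of Col-0. Genotype and table number are thus largely confounded, and the batch term cannot separate them well. Of the 39 calls named, 16 passed under every setting run on single genes, the minimum fold not included, among them ROS1, FLC, TAS2, ARF4, HTT1, HTT2, AT5G35935, EXPA25 and the DCL2 and DCL3 rows, while FT, DFR, LDOX, FWA, SDC, QQS, TAS1A and TAS1B did not pass in some.

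RTL2 overexpression in dcl234 asked what RTL2 changes where DCL2, DCL3 and DCL4 are mutated. FLC was higher, at 8.06 ± 0.715 CPM against 3.04 ± 0.575 CPM in dcl234 (n = 3 each), a 2.64-fold change (SE 0.17 on the log2 scale). QQS fell by 2.30 (SE 0.30), from 4.54 ± 1.37 to 0.916 ± 0.292 CPM. The microRNA precursor MIR822 fell by 2.60 (SE 0.34), from 6.96 ± 0.907 to 1.15 ± 0.114 CPM, and the precursor MIR163 by 1.03 (SE 0.17). Rows that hold precursors together with other genes were lower too: MIR863, MIR850 and AT4G13495 by 1.93 (SE 0.23), and HDA2, MIR860 and FC1 by 1.16 (SE 0.11).

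Of 13 calls, 4 were higher and 9 lower. RTL2 rose by 9.15 (SE 0.21) and AT3G29633 by 3.65 (SE 0.43). The lower calls also included AT3G01345 (−5.12, SE 0.86), AT5G35480 (−1.31, SE 0.19) and ABCI8, a plastid iron-sulfur assembly protein (−0.77, SE 0.08). The adjusted p of edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was 0.00291 for FLC, 0.0042 for MIR822 and for QQS, 0.0485 for MIR163 and for AT3G01345, and 0.000534 for the HDA2 row. RTL2, AT3G29633, FLC, ABCI8 and the 2 precursor rows with several genes passed under every setting run on single genes, the minimum fold not included, and the other 5 of 11 named calls did not pass in at least 1. MIR163 passed in 4 of 15 alternatives and AT3G01345 in 7 of 15, where the log2 of AT3G01345 ran from −7.16 to −3.67. AT3G01345 varied widely between the dcl234 libraries, at 11.8 ± 13.2 CPM. DESeq2 called 50 genes, and 32 passed without dcl234 35S-RTL2 replicate 1.

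Of the 21 lists, 18 held 0 calls in this comparison by edgeR's test. Here 1157 genes had an unadjusted p below 0.05, close to the share of 0.05 that unchanged genes alone would give. FLC was the 1 flowering gene of 6 to pass and QQS the 1 methylation-repressed locus of 6, both also adjusted over the list alone. The 34 silencing factors had a median of 0.12 (camera adjusted p = 0.00367, and adjusted p = 0.577 with an estimated correlation), the 9 sulfur starvation genes −0.58 (camera adjusted p = 0.011, and adjusted p = 0.577 with an estimated correlation), and the construct genes 0.11 (camera adjusted p = 0.0338, and adjusted p = 0.577 with an estimated correlation). Among classes, 2 of 42 microRNA precursors counted alone were lower and 0 higher, also adjusted over the list alone (median −0.15, camera adjusted p = 0.0104, and adjusted p = 0.631 with an estimated correlation). Medians were −0.62 for mitochondrial genes (camera adjusted p = 0.00268, and adjusted p = 0.631 with an estimated correlation) and −0.14 for small nucleolar RNAs (camera adjusted p = 0.0326, and adjusted p = 0.631 with an estimated correlation). The mitochondrial share of counts was 0.00637% in dcl234 replicate 2, 0.00260% and 0.00295% in dcl234 replicates 1 and 3, and 0.00265% to 0.00322% in dcl234 35S-RTL2.

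An unadjusted p below 0.05 for the difference of the RTL2 effect was found for 1123 genes, close to the share of 0.05 that unchanged genes alone would give. The difference of the RTL2 effect between dcl234 and Col-0 passed for 2 genes, both lower. For AT1G67105 it was −4.74 (SE 0.64), with 2.06 (SE 0.44) in Col-0 and −2.68 (SE 0.47) in dcl234. For the row of HDA2, a histone deacetylase, with MIR860 and FC1 it was −1.22 (SE 0.16), with 0.06 (SE 0.11) in Col-0 and −1.16 (SE 0.11) in dcl234. Adjusted p from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was 0.0282 for each difference. By the same test the RTL2 effect on AT1G67105 passed in neither background alone (adjusted p = 0.897 in Col-0 and 0.0626 in dcl234). The next 5 did not pass: RTL2 at 1.58 (SE 0.24), FLC at 1.61 (SE 0.28), AT3G33528 at 3.08 (SE 0.56), MIR822 at −2.54 (SE 0.47) and ACR7 at −0.60 (SE 0.12). RTL2 did pass in 5 of 21 alternatives, among them the replicate block, the compared groups alone, DESeq2 and no filter. Its transcript stood at 1829 CPM in dcl234 35S-RTL2 and 557 CPM in 35S-RTL2. A difference due to the background therefore cannot be told apart from one due to the RTL2 level. Neither call passed with the table number as a batch term (0 genes by edgeR's test, with 764 at an unadjusted p below 0.05). The count was also 0 without any 1 of the Col-0 or 35S-RTL2 libraries, of dcl234 replicates 2 and 3 or of dcl234 35S-RTL2 replicates 2 and 3, and 1 without dcl234 replicate 1, whereas DESeq2 called 11.

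No member of the 21 lists passed for this difference in edgeR's test. Adjusted over the list alone, 1 sulfur starvation gene of 9 was lower. The list's median was −1.47 (camera adjusted p = 1.18e-06, and adjusted p = 0.467 with an estimated correlation). Medians were 0.14 for silencing factors and 0.28 for photosynthesis genes (camera adjusted p = 0.00143 for each, and adjusted p = 0.608 and 0.629 with an estimated correlation). They were −0.10 for microRNA targets (camera adjusted p = 0.0209, and adjusted p = 0.132 with an estimated correlation) and 0.37 for salicylic acid defence genes (camera adjusted p = 0.0438, and adjusted p = 0.608 with an estimated correlation). The mitochondrial genes had a median of −1.64 (camera adjusted p = 6.25e-09, and adjusted p = 0.432 with an estimated correlation), and the microRNA precursors −0.35 (camera adjusted p = 0.0263, and adjusted p = 0.658 with an estimated correlation). In mitochondrial share, 35S-RTL2 replicates 1 and 3 and dcl234 replicate 2 stood above the other libraries of the groups compared, and in the defence list the median of 6 libraries lay over 1 log2 unit from the rest of their group: Col-0 replicate 2 (−1.89), dcl234 replicates 1 and 2 (1.74 and −1.71), dcl234 35S-RTL2 replicates 1 and 2 (−1.05 and 1.16) and 35S-RTL2 replicate 3 (1.06).

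The single truncated DCL1 library was compared with dcl234 with no replicate check, and its spread was taken from the other groups. Salicylic acid defence genes were higher: PR1, a pathogenesis-related protein and marker of this defence, stood at 169 CPM against 0.486 ± 0.29 CPM in dcl234 (n = 3), PR2 at 248 against 4.34 ± 3.29 CPM, and PR5 at 361 against 15.8 ± 3.49 CPM. Among the largest calls were the receptor-like kinase genes CRK23 (6.14, SE 0.91) and CRK37 (5.76, SE 0.67) and the wall-associated kinase gene WAK3 (5.51, SE 0.78). The row of DCL1, PPa1 and MIR838 rose by 3.25 (SE 0.09). CSD1 and CSD2, superoxide dismutases targeted by miR398, fell by 1.44 (SE 0.21) and 1.01 (SE 0.22).

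Of 1205 calls, 1003 were higher and 202 lower. Log2 changes were 8.41 (SE 0.98) for PR1, 7.09 (SE 1.01) for AT3G28510, 5.83 (SE 1.07) for PR2, 5.52 (SE 0.60) for AT1G51890 and 5.43 (SE 0.56) for AT1G51860. The lower calls with the largest change were AT3G01345 (−6.30, SE 1.49), AT2G28090 (−3.45, SE 0.80), MIR822 (−2.51, SE 0.52), IAA32, an auxin-response protein (−2.49, SE 0.49), AT2G23910 (−2.46, SE 0.28), AT2G28085 (−2.44, SE 0.34), AT1G67105 (−2.43, SE 0.68) and AT1G49220 (−2.41, SE 0.62). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the adjusted p was 1.34e-11 for the DCL1 row, 0.000108 for PR1, 0.00357 for PR2 and 0.000734 for CSD1. With the compared groups alone 2942 genes were called (62.7% higher, against 83.2%), and a minimum log2 fold of 1 left 757. Of 38 calls named, 26 passed under every setting run on single genes, the minimum fold not included, and 12 did not in at least 1, among them AT3G01345, AT3G28510, QQS and LHCB2.1.

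Of 19 salicylic acid defence genes, 15 were higher and 0 lower (18 and 0 adjusted over the list alone), with a median log2 of 2.90. PR5 rose by 4.51 (SE 0.36), the regulator CBP60g by 3.71 (SE 0.40), PAD4 by 2.35 (SE 0.27) and ICS1, which makes salicylic acid, by 1.72 (SE 0.18). The camera adjusted p was 1.9e-20, and adjusted p = 0.0141 with an estimated correlation, where no other list of this comparison passed. With 1 library, this test takes its spread from other groups and compares that library with dcl234, not the construct. The list's median log2 CPM was 5.10 in it and ran from 0.71 to 3.01 in dcl234, where replicates 1 and 2 lay 1.74 and −1.71 from the rest of their group. Of 17 clock genes, 8 were higher and 3 lower (8 and 8 adjusted over the list alone), with PRR9 at 3.64 (SE 0.29), CCA1 at 3.62 (SE 0.39), RVE8 at 3.37 (SE 0.32) and LHY at 3.32 (SE 0.30). The clock list's median was −0.71 and its mean 0.32. Of 57 microRNA targets, 3 were higher and 3 lower, also adjusted over the list alone, with SNZ at 1.67 (SE 0.45) and ARF10 at 0.37 (SE 0.09).

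Single calls came from other lists. TAT3, a wound-responsive aminotransferase, was the 1 jasmonate gene of 15 to pass (4.52, SE 0.56), and RD20 the 1 drought gene of 15 (1.26, SE 0.23), both also adjusted over the list alone. MYBL2, a repressor of anthocyanin synthesis, rose by 1.55 (SE 0.37) and F3PRIMEH fell by 0.76 (SE 0.21), 1 higher and 1 lower of 16, also adjusted over the list alone. IG/LINE stood at 0.993 against 0.0595 ± 0.0301 CPM and QQS fell by 1.71 (SE 0.43), 1 higher and 1 lower of 6 methylation-repressed loci, also adjusted over the list alone. The DCL3 row fell by 1.03 (SE 0.28). LHCB2.1 was the 1 photosynthesis gene of 17 to pass (1.43, SE 0.34), with 2 adjusted over the list alone (camera adjusted p = 0.00986, and adjusted p = 0.906 with an estimated correlation). AT4 was the 1 phosphate starvation gene of 9 to pass (−1.35, SE 0.37), also adjusted over the list alone (camera adjusted p = 0.00986, and adjusted p = 0.102 with an estimated correlation). Adjusted over the list alone, 3 of 9 iron deficiency genes were higher (camera adjusted p = 0.00986, and adjusted p = 0.102 with an estimated correlation) and 3 of 6 nucleolar genes lower (camera adjusted p = 0.00986, and adjusted p = 0.415 with an estimated correlation), with 0 over all genes by edgeR's test.

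**Figure D3:**
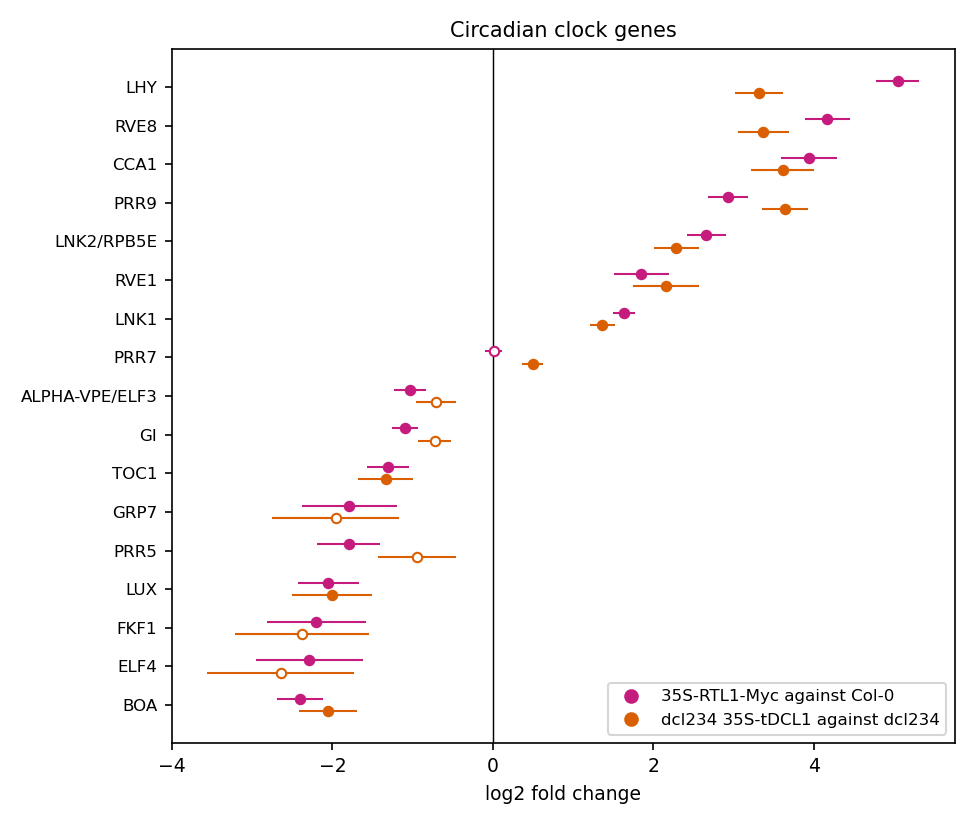
Log2 fold change of 17 circadian clock genes in 35S-RTL1-Myc against Col-0 and in the truncated DCL1 library against dcl234. Bars are standard errors, filled points passed an adjusted p of 0.05 and open points did not. All 17 genes lie on the same side of 0 in both comparisons, with PRR7 at 0.01 in 35S-RTL1-Myc.

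Some lists held 0 calls in every comparison, and the counts in gene classes are to be read beside the share called over all genes. Floral organ markers (8 measured) and seed storage genes (3 measured, too few for camera) had 0 calls in every comparison by edgeR's test. Pseudogenes (220 measured) had 35 higher and 31 lower calls in 35S-RTL1-Myc plants, 13 and 6 in dcl234 and 8 and 1 in the truncated DCL1 library. Transcribed pseudogenes (182 measured) had 36 and 12, 3 and 6, and 18 and 1. Over all genes tested, 29.5%, 4.56% and 5.65% were called in these comparisons. Long non-coding RNAs (4 measured) had 0 calls by edgeR's test in each.

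The overlap of 35S-RTL1-Myc with dcl234, both against Col-0, was measured for genes that changed alike. ROS1, QQS and FT were lower in both. FLC, SDC, GRF9, TAS2, the TAS1C row and 8 trans-acting siRNA targets (ARF3, ARF4, HTT2, RPF3, AT1G62860, AT1G62910, AT1G63130 and AT1G63150) were higher in both. In all, 111 genes were higher in both, where independent lists would share 23.8, and 641 were lower in both, where they would share 119. Opposite calls numbered 26, where 144 would arise. Over 21343 genes, which are not independent replicates, the log2 changes correlated at r = 0.575, against 0.449 in 20 simulations of unchanged groups with the same controls, and had a covariance of 0.387 against 0.0463. The same sign held for 63.0% of genes against 65.0% simulated. The simulated shared calls were 0, but the simulated groups held no changed genes, so few calls could arise at all. That 0 gives no measure of the shared calls that common Col-0 libraries add when both groups differ. Part of the excess may come from the shared Col-0 libraries.

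RTL2 overexpression and rtl2-1, also against the same Col-0 libraries, shared QQS as a lower call and had RTL2 as an opposite one. Their log2 changes correlated at r = 0.509 across genes (0.503 simulated), with a covariance of 0.0870 (0.0463 simulated) and the same sign in 67.5% of genes (66.7% simulated). RTL2 overexpression in Col-0 and in dcl234, which share no libraries, had RTL2 as a higher and QQS as a lower call in both. Across genes their r was 0.236 and Spearman's rho −0.0355.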

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

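The tests below on the clock genes, the mislabelled library and the precursors, apart from the one on precursor rows that hold several genes, were chosen only after the result was seen. The reading of the defence test, of the precursor rows with 1 gene and of the harvest and construct tests on the clock was settled after their values were seen.

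The difference of the RTL2 effect between dcl234 and Col-0 passed a test of the difference itself for 2 genes. For AT1G67105 the difference was −4.74 (SE 0.64), with its level at 4.39 CPM in 35S-RTL2, 1.06 CPM in Col-0, 0.680 CPM in dcl234 35S-RTL2 and 4.44 CPM in dcl234 (n = 3 each). For the row of HDA2, MIR860 and FC1 it was −1.22 (SE 0.16). The adjusted p from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was 0.0282 for both. For AT1G67105 the RTL2 effect passed in neither background alone, and its level ran from 2.03 to 5.83 CPM between the dcl234 libraries. In the truncated DCL1 library, without an RTL2 construct, AT1G67105 changed by −2.43 (SE 0.68) against dcl234 and the HDA2 row by −0.54 (SE 0.16). The RTL2 transcript stood at 557 CPM in 35S-RTL2 and 1829 CPM in dcl234 35S-RTL2. A difference due to the background therefore cannot be told apart from one due to the RTL2 level. Among 100 splits of the 12 libraries, 3 gave as many calls, the real one included. The real split gave 2 and the highest other 4, so the share lies under the threshold of 0.05. The splits exchanged RTL2 and control libraries within each background. They stand for no RTL2 effect in either background, not for an equal effect in both, so they do not exclude chance for the difference. The 2 other splits with as many calls gave more than the real one (3 and 4). The real split gave 0 calls with the table number as a batch term and in 10 of 12 fits that left out 1 library. Over 21 alternatives the difference itself ran from −5.29 to −4.35 for AT1G67105 and from −1.28 to −1.17 for the HDA2 row. A formal check for a single library far from the others was set for groups of 4 to 10 libraries, and 0 groups had that size.

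The other comparisons of 3 libraries with 3 allow 10 splits each, which are too few for a share under 0.05. The real splits gave 2 calls for RTL2 overexpression, 26 for rtl2-1, 973 for dcl234 and 13 for RTL2 overexpression in dcl234. The highest of the other splits gave 0 calls in each, with 1 of 10 splits (the real one) reaching the real count.

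Clock genes shifted in the 35S-RTL1-Myc libraries. Of 16 called clock genes, 7 were higher and 9 lower, and 16 stayed called with RLE scaling, which argues against the scaling of the libraries. The 4 morning genes CCA1, LHY, RVE8 and PRR9 were higher and the 4 evening genes TOC1, GI, LUX and ELF4 lower, 8 of 8 as a harvest at another hour may produce, but the hour of harvest is not in the labels and a shift of it by group cannot be told apart from the group. In the truncated DCL1 library, which lacks the RTL1-Myc construct, 17 of 17 clock genes had the same sign as in 35S-RTL1-Myc, though PRR7 was not called there and 11 of the 17 were called in this library, so a direct effect of RTL1-Myc on the clock is not required by these values, though 1 library does not exclude it. In the other comparisons 3 to 9 of the 17 had the direction seen in 35S-RTL1-Myc. The biological explanation, an effect of RTL1, stays open.

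Salicylic acid defence genes were high in the truncated DCL1 library. A wrong label is argued against by its DCL1 row, which lay 9.17 times above the highest of the other libraries. A defence state that varies between libraries of one group cannot be told apart from an effect of the construct: the list's median in Col-0 replicate 2 lay 1.89 log2 units from the rest of its group, those of dcl234 replicates 1 and 2 lay 1.74 and −1.71, and that of the truncated DCL1 library 3.25 from dcl234, while gene by gene the largest median difference of another library was 0.795 (dcl234 35S-RTL2 replicate 2) against 2.42. The effect of the truncated DCL1 construct itself could not be tested further, since 1 library carries it.

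With RTL2 overexpressed in dcl234, 4 of 68 rows with a microRNA precursor were lower and called, of which MIR163 kept its call in 4 of 15 alternatives. A lower yield of all precursor transcripts, as the whole cause, is argued against by the median of the 68 rows, −0.13 with quartiles of −0.45 and 0.09, where the 4 calls fell by 1.03 or more. Reads of overlapping genes cannot be told apart: for the 2 called rows with 1 gene, MIR822 and MIR163, because the use of strand is not given, and for the 2 with 2 or more genes because the counts do not separate the members. That RTL2 lowers precursors left uncut without DCL2, DCL3 and DCL4 is a hypothesis that stays open. Of the 4 called rows, 1 (HDA2, MIR860 and FC1) had a passing difference of the RTL2 effect. That row was called lower in dcl234 than in Col-0 (log2 −0.57, SE 0.11), where the hypothesis needs a higher precursor. Its counts do not separate MIR860 from HDA2 and FC1, so its direction does not decide on the precursor. MIR822 and the MIR863 row lay higher in dcl234 without passing (adjusted p = 0.0630 and 0.0949 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and 0 of the 4 passed as higher. In the truncated DCL1 library, without an RTL2 construct, MIR822 fell by 2.51 (SE 0.52) against the same dcl234 libraries. There the MIR863 and HDA2 rows stood at −0.67 (SE 0.32) and −0.54 (SE 0.16), and MIR163 at 2.37 (SE 0.20). The fall of MIR822 was therefore not particular to RTL2, as far as 1 library can tell.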

How the results depend on the processing

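The fits whose spread was estimated without rtl2-1 replicate 2 or without the truncated DCL1 library were added after seeing the data, as were the split of the simulated genes by level and the estimated correlation in camera for gene classes, and the other alternatives were planned. Of 234 named gene and comparison pairs under these alternatives, 3252 values were computed: 2900 kept direction and side of the threshold, 306 lost their call, 16 gained one and 30, from 15 pairs of which 0 were called in the main or the changed setting, changed sign. The minimum fold was applied to counts of calls and not to these pairs. Of the pairs, 86 lost a call under at least 1 setting. Organelle genes left out moved no count of calls by over 1.5 times, and nor did RLE scaling or the absence of a filter. The causes of the changes below were not tested, except that a minimum fold can only remove calls. Fewer libraries give less precision, but some counts rose with fewer, as in rtl2-1 from 26 to 54 without rtl2-1 replicate 1.

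DESeq2 called 6 genes for RTL2 overexpression (2 in edgeR), 137 for rtl2-1 (26), 50 for RTL2 overexpression in dcl234 (13) and 11 for the difference of the RTL2 effect (2), where it tested 26844 genes and edgeR 21343. In the simulated RTL2 overexpression, DESeq2 called 27 unchanged genes beside 147 changed ones, and edgeR 4 unchanged among 139 calls. With the compared groups only, rtl2-1 had 1 call, dcl234 3336 and truncated DCL1 2942. With the table number as a batch term, rtl2-1 had 15, dcl234 149 and the difference 0, where 764 genes had an unadjusted p below 0.05. A minimum log2 fold of 1 left 2518 calls for 35S-RTL1-Myc, 518 for dcl234 and 757 for truncated DCL1, and took the genes shared by 35S-RTL1-Myc and dcl234 from 752 to 390.

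Leaving out each replicate in turn gave 2 to 3 calls for RTL2 overexpression, 12 to 54 for rtl2-1, 3939 to 5212 for 35S-RTL1-Myc, 282 to 562 for dcl234, 9 to 32 for RTL2 overexpression in dcl234, 809 to 939 for truncated DCL1 and 0 to 2 for the difference. In rtl2-1 the lowest was without Col-0 replicate 3 and the highest without rtl2-1 replicate 1, in dcl234 without dcl234 replicates 1 and 3, and the 32 without dcl234 35S-RTL2 replicate 1.

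With the spread estimated without rtl2-1 replicate 2 the counts were 2, 7564, 1321, 16, 1601 and 3 for RTL2 overexpression, 35S-RTL1-Myc, dcl234, RTL2 overexpression in dcl234, truncated DCL1 and the difference. With an estimated correlation in camera, the fixed lists that passed went from 4 to 0 for RTL2 overexpression, 6 to 0 for rtl2-1, 5 to 1 for 35S-RTL1-Myc, 4 to 0 for dcl234, 3 to 0 for RTL2 overexpression in dcl234, 5 to 1 for truncated DCL1 and 5 to 0 for the difference.

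The replicate number as a block gave 2 calls for RTL2 overexpression, 37 for rtl2-1, 6832 for 35S-RTL1-Myc, 1156 for dcl234, 13 for RTL2 overexpression in dcl234 and 3 for the difference. No block could be fitted for truncated DCL1, whose title has no replicate number. The labels do not say that the numbers pair the libraries, so the main fit did not use them as a block. Of 14 same-numbered pairs 7 had deviations correlated over 0.1, with a range from −0.302 to 0.437, which does not settle whether they are paired. The 7 were the pairs with Col-0 of replicates 1 and 3, at 0.187 to 0.437, and in 8 pairs the libraries correlated best with their own number, a hint from the data and not from the design. In the simulated difference of the RTL2 effect over 21141 genes, 75.8% of 4-fold, 35.8% of 2-fold and 7.46% of 1.5-fold changes were called. Of its 4-fold changes, 61.1% were called in genes below the median level and 93.3% above it.

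The sign changes lay in RTL1, RTL2 and the DCL rows, in comparisons where they were not called, and their cause was not tested. With the table number as a batch term, log2 values were 0.16 for RTL1 and −0.028 for DCL4 with RTL2 overexpression, and 0.25 for RTL1 and 0.013 for the DCL1 row in dcl234, where the DCL1 row stood at 0.0013 without a filter. With each replicate left out in turn, RTL1 ran from −0.57 to 0.18 and DCL4 from −0.066 to 0.17 with RTL2 overexpression. In rtl2-1 the DCL2 row ran from −0.12 to 0.025, the DCL3 row from −0.30 to 0.0096 and DCL4 from −0.052 to 0.14. In 35S-RTL1-Myc, RTL2 ran from −0.18 to 0.47 and the DCL1 row from −0.078 to 0.0093, and in dcl234 RTL2 ran from −0.011 to 0.24 and the DCL1 row from −0.041 to 0.0049. With RTL2 overexpression in dcl234, RTL1 ran from −0.91 to 3.56, the DCL1 row from −0.019 to 0.027 and the DCL2 row from −0.025 to 0.0095. RTL1 ran from −0.41 to 3.48 in truncated DCL1 and from −0.70 to 3.78 for the difference. RTL1 had few counts in dcl234, at 0, 1 and 20 in replicates 1, 2 and 3, and their part in these changes was not tested.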

Other observations

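The genes of the opening paragraphs and the test on FT were chosen only after the result was seen, and so was the comparison of 35S-RTL1-Myc with truncated DCL1. The other tests in this part were set before their results were seen, though the test of opposite signs was read anew afterwards.

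QQS, AT3G01345 and AT5G35935 varied across the groups in patterns that no single comparison shows. QQS was highest in Col-0, at 10.7 CPM, and lay between 0.916 and 4.54 CPM in the other 6 groups. AT3G01345 stood at 284 CPM in rtl2-1, 11.8 CPM in dcl234 and at most 0.614 CPM in each other group. AT5G35935 stood at 0.555 CPM in rtl2-1, 3.62 CPM in Col-0, 7.36 CPM in 35S-RTL2, 11.3 CPM in 35S-RTL1-Myc and 33.6 CPM in dcl234. FLC stood at 0.476 CPM in rtl2-1, 1.09 CPM in Col-0, 3.04 CPM in dcl234, 6.98 CPM in 35S-RTL1-Myc and 8.06 CPM in dcl234 35S-RTL2.

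MicroRNA precursors moved in 35S-RTL1-Myc plants in both directions. MIR163 stood at 3.48 CPM in Col-0 and 19.1 CPM in 35S-RTL1-Myc plants, where it rose by 2.46 (SE 0.17) on the log2 scale. It stood at 3.22 CPM in dcl234 and 16.6 CPM in the truncated DCL1 library, and rose by 2.37 (SE 0.20) there. The row of NRT2.7 and MIR398c, whose members the counts do not separate, rose by 1.98 (SE 0.21) in 35S-RTL1-Myc and 1.93 (SE 0.24) in truncated DCL1. MIR822 fell by 2.14 (SE 0.42) in 35S-RTL1-Myc plants and MIR162a by 1.67 (SE 0.18). Of 42 precursors counted alone, 5 were higher and 4 lower in 35S-RTL1-Myc, where 29.5% of all genes were called. In the truncated DCL1 library 3 were higher and 1 lower.

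If loss and overexpression of RTL2 moved the same genes in opposite directions, most of the 25 genes called in rtl2-1 other than RTL2 would have opposite signs in 35S-RTL2. Of the 25, 10 had, fewer than the bound of 13 set beforehand. That bound left out the shared Col-0 libraries, which alone gave the same sign in 66.7% of genes in simulations, so the count argues neither for nor against the hypothesis.

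Genes lower in dcl234 may vary with FT between libraries of one group. Over 9 libraries of Col-0, 35S-RTL2 and rtl2-1, the mean of 811 genes lower in dcl234, apart from FT, and FT itself correlated as deviations from group means at r = 0.907 (exact permutation p = 0.0370, two-sided) and Spearman's rho 0.867 (exact permutation p = 0.0324), over 216 arrangements within groups, which allow no p below 0.00463. This is 1 relation computed in its family, so the Benjamini-Hochberg adjusted values equal the raw ones, but FT was singled out after per-library values of other genes had been looked at. These p-values take libraries of different groups as independent, yet the 3 replicate 1 libraries lay above and the 3 replicate 3 libraries below their group means in both measures, so they are not valid if the replicate number marks a shared set. With the replicate number as a term r was 0.896. With the table number as a batch term r was 0.919, and each batch held at most 5 libraries, too few for a value within it. Without the 2 libraries farthest in FT, 35S-RTL2 replicate 3 and rtl2-1 replicate 3, r fell to 0.670, under the 0.7 set for it, so the relation partly rests on those libraries and the hypothesis stays open.

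The 35S-RTL1-Myc and truncated DCL1 comparisons, which share no libraries, had 514 genes higher in both, where independent lists would share 148, and 157 lower in both, where they would share 29.7. Opposite calls numbered 58, where 177 would arise. Over all genes r was 0.239, and over the 6289 genes called in 35S-RTL1-Myc r was 0.415, with the same sign in 78.4%. That shared changes follow the shift of the clock is a hypothesis which this value leaves open: it may reflect a shared hour of harvest or any other state the libraries share, and it rests on a single truncated DCL1 library.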
